A study of Gallus gallus with 36 samples.

How the data were processed

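Peripheral blood leukocyte RNA of male broiler chickens was measured on 36 two-colour oligonucleotide arrays of 45220 spots, 4 arrays for each of 9 groups on 9 slides. Per the labels, 400 ng of total RNA was turned into labelled cRNA, and the RNA of non-vaccinated unchallenged birds of day 1 was the other channel of every array. Replicates 1 and 3 of each group had their own RNA in Cy3 and replicates 2 and 4 in Cy5. Whether the reference was a pool is not given in the sources used here.

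Per the file headers, each deposited scan gives the pixel intensity of every spot and of its local background in the red and green channels, read with GenePix Pro 7.0.4 without normalization. Per the file headers the deposited scans also give the percent of saturated pixels of each spot. The deposited table for the whole series holds 24387 values per array, which were taken as log2 ratios centred by the authors. The authors' base, direction and filter are not stated; the values had medians of -0.0177 to 0.0199 and correlated at 0.669 to 0.915 across spots with log2 ratios of own over reference RNA from the scans. Scanner gains differed between arrays, from 656 to 786 in red and 506 to 588 in green. Median signals were 63 to 126 in red and 72 to 117 in green, over median backgrounds of 56 to 107 and 57 to 76.

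Choices of tests, gene lists, the rule for named genes and the alternatives were made before the data were examined, except where a choice is said to have been added. They assumed Agilent Feature Extraction columns and spot flags, but the scans were GenePix files in which 0 spots had a flag, so mean spot signals and median backgrounds of GenePix were used and no spot was left out by flag. In place of the scanner software's detection flag, a spot was above background where its mean signal less its local background exceeded the median plus 3 median absolute deviations of 153 negative control spots in that channel. Signals were corrected with normexp (offset 50), normalised by loess within each array with the 1417 control spots at weight 0, averaged over the spots of a probe and turned to own over reference RNA.

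Probes were kept where they were above background in the own RNA channel on at least 3 of 4 arrays of any group or in the reference channel on at least 18 arrays, which left 19851 of 42033 probes. Each gene symbol was represented by its brightest kept probe and each unnamed probe by itself, giving 18159 genes or probes tested, 1640 of them with a symbol. Symbols came from the array annotation and were brought up to date with a RefSeq gene table of the chicken; no genomic coordinates were used. Between 32.9% and 50.4% of probes were above background in the own RNA and between 33.6% and 54.7% in the reference on an array. The number of arrays limits the precision of every value.

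Differences were tested with limma 3.58.1 in R 4.3.3, with 9 group means and a dye term fitted to all 36 arrays and Benjamini-Hochberg adjustment over genes within each of 16 comparisons. Tests were two-sided, and an adjusted p below 0.05 passed. With no change at all, 908 genes would have an unadjusted p under 0.05. Errors of differences are standard errors from the fit, and errors of group means are SDs of 4 arrays. Named genes were up to 12 each way with a symbol, the largest changes among those past the threshold and all 4 arrays on the same side, for the comparisons of non-vaccinated challenged birds, up to 5 each way elsewhere, and members of the lists.

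The 18 lists were inflammatory cytokines and chemokines, Toll-like receptor and NF-kB signalling, interferon-stimulated genes, antigen presentation, lysosome and phagosome, apoptosis, cell cycle, heat shock and protein folding, heterophil granule and migration, acute phase and iron handling, oxidative phosphorylation, ribosomal proteins, and markers of T cells, B cells, monocytes and macrophages, erythroid cells, thrombocytes, and NK and cytotoxic cells. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a comparison, with an estimated correlation and fry beside it. Most lists were measured only in part, with 6 of 36 genes of the heterophil, 12 of 47 of the Toll-like receptor and 8 of 38 of the T cell list. EXFABP, LYZ, GFI1B and IFNG are each in more than 1 list.

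The replicate number and the slide were examined as batches, and each was tried as a block. Arrays with the same number correlated at 0.33 to 0.81 over genes in 11 of 11 comparisons, and at -0.08 to 0.59 after the dye effect was removed. The number carries the dye orientation, so the block also adjusts for the dye. The main fit kept the dye term alone, as chosen beforehand, because the labels do not say what a number shares. It thus leaves out the pairing that remains after the dye effect. Values with the number as a block are given beside results that it moved. The first principal component held 41.2% of the variance and separated the dye orientations. A scan date was given for too few arrays to be tested. Alternatives were no background subtraction, median centring, scaling between arrays, no filter or a stricter one, the mean of a gene's probes, slide as a random (statmod 1.5.0) or fixed block, the replicate block, no dye term, array weights, the authors' values, only the groups compared, other set tests and each array left out. Spot medians and the mean of the 3 unchallenged groups as control were added after seeing the data.

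The fit was tested on simulated data, with 50 genes of each size changed among 18159: 16% of changes of 0.5, 50% of 1.0, 82% of 1.5 and 90% of 2.0 on the log2 scale were recovered, 0 with the wrong sign, and 14 of 133 calls were false. A simulated shift of -0.5 in the 14 ribosomal genes gave a camera adjusted p of 4.2e-15, with 0 other lists called. The simulated noise was independent between genes and between arrays. It lacked the correlation between genes and between arrays of the same slide or number. The simulation therefore cannot show how often the fit or camera errs where such correlation is present. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 in Python 3.11.15.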

Results

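Gene expression was measured in peripheral blood leukocytes of male broiler chickens, some of them vaccinated at 2 weeks of age and some challenged at 4 weeks with avian pathogenic Escherichia coli, a bacterium that causes respiratory and systemic disease in poultry. Blood was taken 1 or 5 days after the challenge. Non-vaccinated challenged birds were separated by their internal lesions into mild and severe pathology. The data were 36 arrays in 9 groups of 4, namely vaccinated unchallenged, vaccinated challenged, mild and severe birds on day 1, and these same 4 kinds of bird plus non-vaccinated unchallenged birds on day 5. RNA of non-vaccinated unchallenged birds of day 1 was the reference on every array, so a comparison with it is a log ratio against 0 that leaves out the control's own spread. Between 32.9% and 50.4% of probes were above background in the birds' own RNA on an array. Of 18159 genes or probes tested, 1640 had a gene symbol, and 4 arrays per group limit the precision of every value. The labels do not say whether replicates were separate birds or pools, so p-values measure the spread between these samples. The RNA was of mixed leukocytes and no cell counts were used. A gene that rose or fell therefore cannot be read as a change within cells, nor a marker list as a number of cells.

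Severe pathology on day 1 was set against the unchallenged day 1 reference to ask what the circulating leukocytes express in the birds most affected. Antimicrobial genes of heterophils, the avian counterpart of neutrophils, were among the most raised. The defensin DEFB4A rose by 4.75 ± 0.77 on the log2 scale (SE, n = 4), or 26.8-fold, with a limma adjusted p of 0.00017. Its spots were saturated on 2 of the 4 arrays, so this fold is not exact, and with slide as a fixed block its log2 difference was 3.90. The goose-type lysozyme LYG2 rose by 4.24 ± 0.72, the lysozyme LYZ by 3.49 ± 0.43, the siderophore-binding lipocalin EXFABP by 2.51 ± 0.76 and the cathelicidin CATH1 by 2.41 ± 0.39. Of the 6 measured genes of the heterophil granule and migration list, 5 rose over all genes tested and 5 adjusted over the list alone, while CATH2 stood at -0.27 ± 0.38. The list's mean shift was 2.86 (camera adjusted p = 1.1e-06; adjusted p = 0.090 with an estimated correlation). TF, the iron-binding ovotransferrin, rose by 2.81 ± 0.75. In the acute phase and iron handling list, with 4 measured genes and no set test, 2 rose over all genes and 3 adjusted over the list alone, SOD2 at 0.53 ± 0.21 being the third. HIF1A stood at 0.13 ± 0.18.

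Other genes that rose in severe birds on day 1 were ZC3H13 (5.33 ± 0.82), the tetraspanin TSPAN8 (3.88 ± 0.59), the ectoenzyme BST1 (2.86 ± 0.66), the cyclic GMP phosphodiesterase PDE5A (2.37 ± 0.41), ANGPTL5 (2.08 ± 0.53) and the kinesin KIF21A (2.03 ± 0.55). In the reference channel PDE5A was above background on 1 of the 4 arrays, and ANGPTL5 and KIF21A on 2. Saturated spots were present in severe birds on 2 of 4 arrays for ZC3H13, DEFB4A and EXFABP and on 1 for LYZ. CD3D and CD74 were saturated in the reference channel on 2 and 1 of these arrays. The differences of these genes are therefore not exact. CD74, the invariant chain of MHC class II and the only measured member of the antigen presentation list, fell by 1.90 ± 0.26 (limma adjusted p = 3.2e-05). ELAVL1 fell by 2.18 ± 0.39. Other named genes that fell included AEBP2, KCNK1, DKK3, FOXP1, PPP3CA, HPS3, DPYSL2, ANKH and SOCS4, from -1.57 for AEBP2 to -1.12 for SOCS4. HPS3 was above background on 2 of the 4 severe arrays.

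Among 12 genes of the Toll-like receptor and NF-kB list, 3 rose in severe birds on day 1, over all genes and adjusted over the list alone: the avian receptor TLR15 (1.54 ± 0.41), the TLR4 co-receptor LY96 (0.88 ± 0.18) and the kinase MAPK3 (0.53 ± 0.12). The list's mean shift was 0.36 (camera adjusted p = 0.016; adjusted p = 0.43 with an estimated correlation), and with slide as a fixed block its adjusted p was 0.054. Without severe replicate 1 or 3 its mean was 0.31 and it did not pass (camera adjusted p = 0.063 and 0.058). The 14 ribosomal protein genes had a mean of -0.32 (camera adjusted p = 0.016; adjusted p = 0.70 with an estimated correlation). Of these, 3 fell over all genes and 4 adjusted over the list alone, with RPL14 at -0.70 ± 0.23 and RPL32 at -0.62 ± 0.19. Centring each array on its median in place of loess gave an adjusted p of 0.42, and without severe replicate 1 the mean was -0.14 (camera adjusted p = 0.32). Against the same reference this list had means of -0.20 in mild and -0.22 in vaccinated unchallenged birds of day 1. The fall was therefore not particular to severe birds. Of 8 T cell markers, CD4 (-0.94 ± 0.25) and CD3D (-0.93 ± 0.19) fell and CD28 rose (0.69 ± 0.22). Adjusted over the list alone 1 rose and 3 fell, and the camera adjusted p was 0.29. Probes of CD28 and of CD3D differed, so that CD28 was at -0.15 with the mean of its probes and CD3D at 0.00 in the authors' deposited values; neither passed with the mean of its probes (limma adjusted p = 0.51 and 0.53). In the apoptosis list FAS (0.90 ± 0.21) and BID (0.66 ± 0.20) rose, 2 of 7 over all genes, and adjusted over the list alone 2 rose and 2 fell. Single members that passed in other lists were the co-chaperone FKBP5 (1.19 ± 0.29), the coagulation factor F13A1 (1.19 ± 0.25), HELZ2 (0.63 ± 0.13), SLC25A37 (0.52 ± 0.16), MANBA (-0.49 ± 0.11), and the replication genes UHRF1 (-0.75 ± 0.23) and MCM6 (-0.51 ± 0.13). With slide as a fixed block CD28 (limma adjusted p = 0.078), BID (0.052), UHRF1 (0.083), RPL21 (0.051) and SLC25A37 (0.076) did not pass.

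In all, 1036 genes or probes were higher and 995 lower in severe birds on day 1 than in the reference by limma, 2031 together. Under the alternatives the share that was higher ran from 45.3% with slide as a fixed block to 71.7% with only the groups compared. The replicate block gave 3481, leaving out severe replicate 1 gave 894 and leaving out replicate 3 gave 836. Against the mean of the 3 unchallenged groups on the arrays, a control chosen after seeing the data, 501 were called. Of the named genes and list members called against the reference, 14 passed there and 28 did not, the 28 with their direction kept. DEFB4A was at 5.21, LYG2 at 4.44, LYZ at 3.82, CATH1 at 2.80 and CD74 at -1.77, all past the threshold. The values of DEFB4A and LYZ, saturated on some severe arrays, are not exact here either. TF (2.74, limma adjusted p = 0.080), EXFABP (2.47, 0.13) and BST1 (2.64, 0.056) did not pass, with differences close to those against the reference. Nor did TLR15 (1.13, limma adjusted p = 0.20), ELAVL1 (-1.49, 0.069), FAS (0.63, 0.15), FKBP5 (0.91, 0.14), F13A1 (0.99, 0.053) or CD4 (0.057). Differences far smaller than against the reference included BID at 0.33 and MANBA at -0.14.

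Mild pathology on day 1 was compared with the same reference. No gene with a symbol passed; 3 unnamed features were higher and 11 lower by limma, among them TC190629 at 3.01 and CR522995 at -1.10. These IDs were chosen after their values were seen. The 6 heterophil genes had a mean of 1.40 (camera adjusted p = 0.00067; adjusted p = 0.26 with an estimated correlation), none passed over all genes, and 3 rose adjusted over the list alone: LYG2 (2.23 ± 0.72), DEFB4A (2.09 ± 0.77) and LYZ (1.42 ± 0.43). Replicate 3 stood at 3.31 on this list and the other 3 arrays at 0.58 to 1.01. Without replicate 3 the mean was 0.74 and the list did not pass (camera adjusted p = 0.17). The Toll-like receptor list had a mean of 0.28 (camera adjusted p = 0.015; adjusted p = 0.31 with an estimated correlation), with 0 genes over all and 3 adjusted over the list alone, LY96 (0.73 ± 0.18), MAPK3 (0.40 ± 0.12) and TLR15 (1.27 ± 0.41). Without replicate 3 its mean was 0.16 (camera adjusted p = 0.26). All 8 T cell markers were below 0, with a mean of -0.34 (camera adjusted p = 0.0073; adjusted p = 0.26 with an estimated correlation; 0.17 with slide as a fixed block), and 1, CD3D at -0.58 ± 0.19, fell adjusted over the list alone. Without replicate 1 the T cell mean was -0.18 (camera adjusted p = 0.21). Ribosomal protein genes had a mean of -0.20 (camera adjusted p = 0.015; adjusted p = 0.61 with an estimated correlation; 0.20 with median centring), with 0 of 14 past the threshold over all genes or adjusted over the list alone. Without replicate 1 this mean was -0.08 (camera adjusted p = 0.46) and without replicate 3 it was -0.15 (0.19). The count of 14 became 472 with the replicate block, 30 with slide as a fixed block and 0 against the 3 unchallenged groups. It was 0 without mild replicate 1, 0 without replicate 3, 9 without replicate 2 and 7 without replicate 4.

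**Figure D1:**
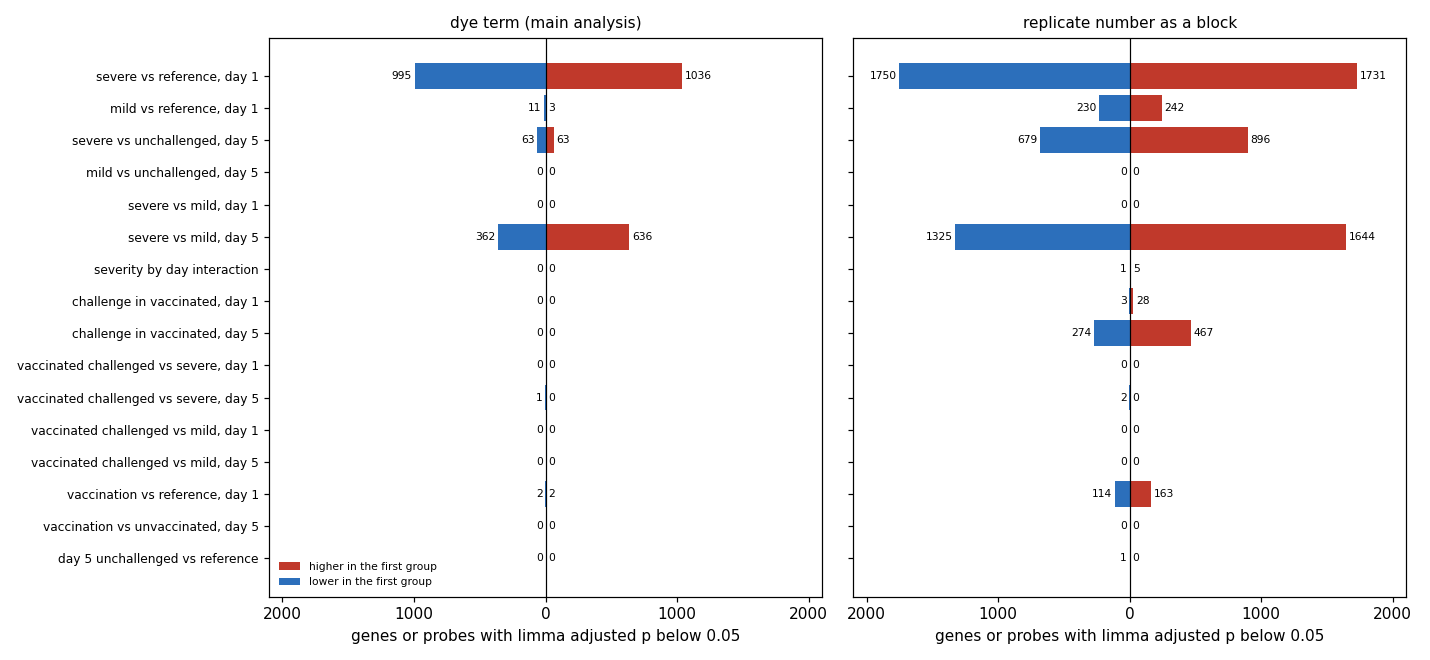
Genes or probes with a limma adjusted p below 0.05 in each of the 16 comparisons, drawn to the right where higher and to the left where lower in the group named first. The left panel has the dye term and the right panel the replicate number as a block; severe birds against the reference on day 1 gave 2031 in the left panel and 3481 in the right.

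Severe and mild birds on day 1 were then compared directly. No gene passed by limma, with 806 at an unadjusted p under 0.05 and 0 with the replicate block or with slide as a fixed block. The heterophil list had a mean of 1.45 (camera adjusted p = 0.00041; adjusted p = 0.40 with an estimated correlation). Of its 6 genes 3 rose adjusted over the list alone and 0 over all genes: DEFB4A was 2.65 ± 1.08 higher, LYZ 2.07 ± 0.61 and CATH1 1.70 ± 0.55. The differences of DEFB4A and LYZ are not exact, since they were saturated on 2 and 1 of the severe arrays. CD74 differed by -1.24 ± 0.37 and did not pass over all genes (limma adjusted p = 0.88). With slide as a fixed block the list's mean was 0.78 (camera adjusted p = 0.52), while its camera call remained without each of the 8 arrays in turn. Slide 5 was the 1 slide that held both groups, with severe replicate 2 and mild replicate 3 in opposite dyes. There the severe array, the lowest of its group at 2.14, differed from the mild one, the highest of its group at 3.31, by -1.17. Without mild replicate 3 the gene count was 2.

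On day 5, severe birds were compared with unchallenged non-vaccinated birds of the same day. The transcriptional repressor NFIL3 rose by 2.60 ± 0.53 (SE, n = 4 per group; limma adjusted p = 0.021), from 0.91 ± 0.68 (SD) in unchallenged to 3.52 ± 0.48 (SD) in severe birds. The palmitoyltransferase ZDHHC20 (1.95 ± 0.48), the Rac exchange factor PREX1 (1.86 ± 0.36), CMBL (1.83 ± 0.28), the proteasome subunit PSMB5 (1.31 ± 0.30), GABRB2 (1.01 ± 0.25) and SAYSD1 (0.65 ± 0.16) also rose. CMBL and GABRB2 were above background on 1 of 4 unchallenged arrays. The microtubule regulator STMN1 (-1.72 ± 0.42), the T cell receptor component CD3D (-1.16 ± 0.28), the calcium-binding protein CALB2 (-1.02 ± 0.23) and the proteasome assembly factor PSMG3 (-0.97 ± 0.24) fell. CD3D was saturated on 1 unchallenged array, so its difference is not exact. CD3D, which did not pass with the mean of its probes (limma adjusted p = 0.36) or with slide as a fixed block (0.061), was the 1 of 8 T cell markers that fell over all genes. In all 3 fell adjusted over the list alone, with CD3E at -1.73 ± 0.45 and CD4 at -1.30 ± 0.36. The list's mean was -0.44, its median 0.00 and its camera adjusted p 0.17.

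The heterophil list was 1.83 higher in severe than in unchallenged birds on day 5 (camera adjusted p = 0.0020; adjusted p = 0.38 with an estimated correlation), with 0 of 6 over all genes and 4 adjusted over the list alone: LYG2 (3.73 ± 1.01), EXFABP (2.52 ± 1.08), LYZ (1.82 ± 0.61) and CATH2 (1.38 ± 0.54). EXFABP was saturated on all 4 severe arrays and 1 unchallenged array, so its difference is not exact. On slide 8, which held both groups, the heterophil list differed by 1.88. The Toll-like receptor list was 0.61 higher (camera adjusted p = 0.0020; adjusted p = 0.32 with an estimated correlation), with 0 of 12 over all genes and 5 adjusted over the list alone, among them TLR15 (1.99 ± 0.58) and TLR7 (1.93 ± 0.57). In total 63 genes or probes were higher and 63 lower, 126 together. This balance changed with the probes and arrays used: 25 were higher and 59 lower with only probes above background in both channels of all arrays, 57 and 134 without unchallenged replicate 4, and 373 and 227 without unchallenged replicate 2. The replicate block gave 1575 and slide as a fixed block 1009, and between-array scaling left 1. The count was 3, 600, 8 and 191 without unchallenged replicates 1, 2, 3 and 4, and 20, 14 and 37 without severe replicates 2, 3 and 4.

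Mild birds on day 5 did not differ from unchallenged birds in any single gene by limma (0 genes, 418 at an unadjusted p under 0.05, 0 with the replicate block, 1 with slide as a fixed block). NFIL3 averaged 0.16 ± 0.50 (SD) in mild and 0.91 ± 0.68 (SD) in unchallenged birds. LYG2 differed by -0.78 ± 1.01, TLR15 by -0.05 ± 0.58 and CD4 by 0.27 ± 0.36. Ribosomal protein genes had a mean of -0.22 (camera adjusted p = 0.050; adjusted p = 0.58 with an estimated correlation; 0.17 with slide as a fixed block), just inside the threshold before rounding, with 0 of 14 over all genes or adjusted over the list alone. Without unchallenged replicate 3 the mean was -0.06 (camera adjusted p = 0.60). The list did not pass either without unchallenged replicate 2 (camera adjusted p = 0.16) or mild replicate 1 (0.13), 2 (0.13) or 4 (0.063).

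Within day 5, severe birds differed from mild birds in 998 genes or probes, 636 higher and 362 lower. LYG2 was 4.51 ± 1.01 higher (limma adjusted p = 0.011) and LYZ 2.38 ± 0.61. The vasoactive peptide ADM rose by 3.77 ± 0.81, NFIL3 by 3.36 ± 0.53 (limma adjusted p = 0.00091), the signalling regulator RGS2 by 3.08 ± 0.85, the lipolysis inhibitor G0S2 by 2.86 ± 0.62 and the chemokine CCL3 by 2.71 ± 0.81. ZC3H13 (3.83 ± 1.16), TSPAN8 (3.64 ± 0.84), BST1 (3.44 ± 0.94), BBX (2.86 ± 0.83), KIF21A (2.72 ± 0.78) and SPSB1 (2.40 ± 0.68) rose too. TSPAN8 was above background on 2 of 4 mild arrays and ADM on 3. The T cell receptor component CD3E fell by 2.43 ± 0.45 (limma adjusted p = 0.0034) and the co-receptor CD4 fell by 1.57 ± 0.36. STMN1 (-1.79 ± 0.42), KCNK1 (-1.77 ± 0.43), glycerol kinase GK (-1.76 ± 0.33) and the purine synthesis enzyme ADSL (-1.67 ± 0.38) also fell, as did ITGB1, GIPC2, CALM2, ASH1L, LGALSL and SSBP3, from -1.28 for ITGB1 to -1.14 for SSBP3.

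Of the 8 T cell markers, 3 fell in severe against mild birds on day 5 over all genes and 3 adjusted over the list alone, the other being CD3D at -1.13 ± 0.28, saturated on 1 mild array, which was 0.13 in the authors' deposited values and did not pass with the mean of its probes (limma adjusted p = 0.39). CD8A (0.09 ± 0.18), LCK (0.08 ± 0.22) and CD28 (0.17 ± 0.31) did not pass. The list's mean was -0.59 and its median 0.03, and the camera adjusted p was 0.082. The Toll-like receptor list was 0.66 higher (camera adjusted p = 0.0018; adjusted p = 0.27 with an estimated correlation), 3 of 12 rose over all genes and 6 adjusted over the list alone, led by TLR15 (2.04 ± 0.58), TLR7 (1.94 ± 0.57) and LY96 (1.27 ± 0.26). The heterophil list was 2.27 higher (camera adjusted p = 0.0012; adjusted p = 0.27 with an estimated correlation), 2 of 6 rose over all genes and 4 adjusted over the list alone. Oxidative phosphorylation genes were 0.47 higher (camera adjusted p = 0.026; adjusted p = 0.47 with an estimated correlation), with 0 of 10 over all genes and 2 adjusted over the list alone, NDUFB8 (1.03 ± 0.34) and ATP5J2 (0.72 ± 0.26). Without mild replicate 1 or severe replicate 4 that list did not pass (camera adjusted p = 0.068 and 0.069). PIK3AP1, 1 of 3 measured B cell markers, fell by 0.97 ± 0.25. On slide 2, which held both groups, the heterophil list differed by 2.57. EXFABP, a gene of that list, was saturated on all severe arrays of day 5, so the list's differences here are not exact. With slide as a fixed block LYG2 (limma adjusted p = 0.052), ZC3H13 (0.051), SPSB1 (0.055), CALM2 (0.051), ASH1L (0.12), SSBP3 (0.086), LYZ (0.086), TLR15 (0.12) and CD3D (0.085) did not pass. The replicate block gave 2969 genes. Median centring gave 501 higher and 591 lower and moved the median of all genes to -0.12. The count was 310 and 638 and 646 without severe replicates 3, 2 and 4, and 458, 367 and 390 without mild replicates 1, 2 and 4.

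**Figure D2:**
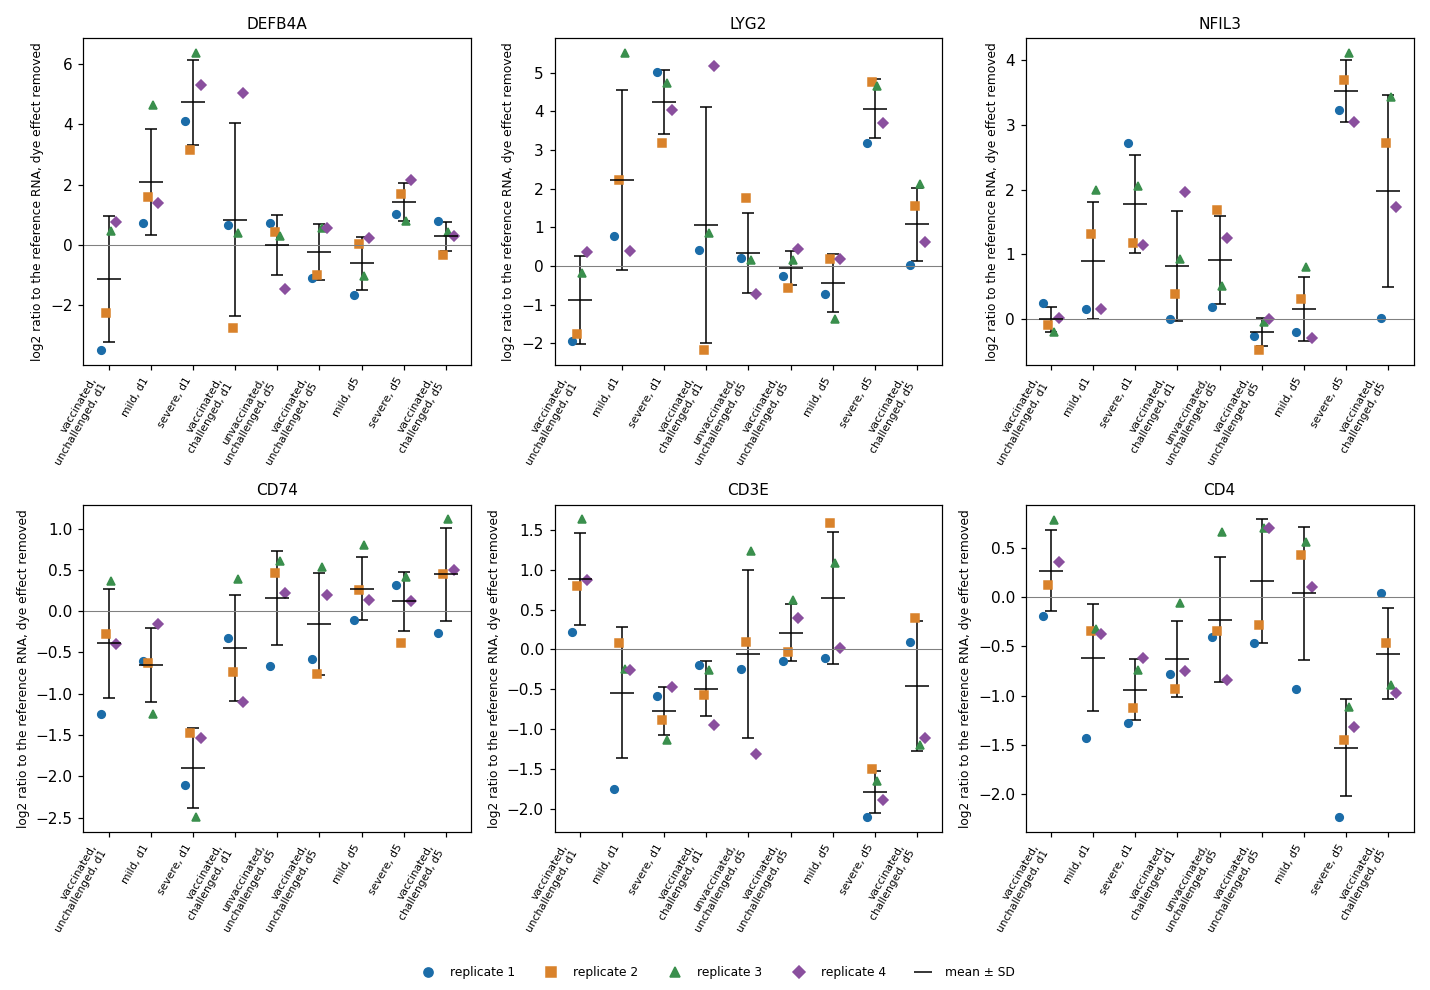
Log2 ratio to the reference RNA, with the dye effect removed, of 6 genes in each of the 36 arrays (points, by replicate number) with the mean and SD of the 4 arrays of a group. In severe birds LYG2 averaged 4.24 on day 1 and 4.07 on day 5, CD74 averaged -1.90 on day 1 and CD3E -1.78 on day 5.

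Whether the difference between severe and mild birds itself differed between days was tested as an interaction. No gene passed by limma, with 1528 at an unadjusted p under 0.05, 6 with the replicate block and 2 with slide as a fixed block. The Toll-like receptor list differed more on day 5 by 0.58 (camera adjusted p = 0.028; adjusted p = 0.44 with an estimated correlation). The T cell list differed by -0.64 (camera adjusted p = 0.028; adjusted p = 0.44 with an estimated correlation), with an adjusted p of 0.051 with the replicate block and 0.37 with slide as a fixed block, where the Toll-like receptor list had 0.068. The T cell list did not pass without mild replicate 1 (camera adjusted p = 0.17) or severe replicate 4 (0.096) of day 1, nor without severe replicate 1 (0.14) or 2 (0.066) or mild replicate 2 (0.064) or 3 (0.10) of day 5. The Toll-like receptor list did not pass without mild replicate 3 (camera adjusted p = 0.097) or severe replicate 4 (0.078) of day 1 or severe replicate 2 (0.066) of day 5. Over all genes 0 members of either list passed, and adjusted over the list alone 1 T cell marker was lower.

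Challenge of vaccinated birds was compared with no challenge on each day. On day 1 the heterophil list was 1.43 higher (camera adjusted p = 0.0062; adjusted p = 0.85 with an estimated correlation), with DEFB4A at 1.97 ± 1.08 and LYZ at 1.63 ± 0.61 and 0 of 6 past the threshold either over all genes or adjusted over the list alone. The challenged arrays stood at 0.24, -1.24, 0.90 and 2.73, the last being replicate 4. Without it the mean was 0.71 (camera adjusted p = 0.30), and without unchallenged replicate 1 it was 1.03 (0.13). With slide as a fixed block that list's adjusted p was 0.17, and on slide 4, which held both groups, it differed by 0.10. No gene passed by limma on day 1, with 1231 at an unadjusted p under 0.05, 31 with the replicate block and 17 with slide as a fixed block. On day 5 the Toll-like receptor list was 0.50 higher (camera adjusted p = 0.020; adjusted p = 0.46 with an estimated correlation), with 0 of 12 over all genes and 2 adjusted over the list alone, TLR15 (1.89 ± 0.58) and LY96 (0.75 ± 0.26). It did not pass without unchallenged replicate 1 (camera adjusted p = 0.058) or 3 (0.082) or challenged replicate 2 (0.064) or 3 (0.10). Cell cycle genes had a mean of -0.28 (camera adjusted p = 0.015; adjusted p = 0.46 with an estimated correlation), with 0 of 12 over all genes and 3 lower adjusted over the list alone; MCM6 was at -0.71 ± 0.18 and UHRF1 at -1.12 ± 0.33. With slide as a fixed block both lists had an adjusted p of 0.067, and without unchallenged replicate 3 the cell cycle list had a camera adjusted p of 0.10. Ribosomal protein genes had a mean of -0.33 (camera adjusted p = 0.013; adjusted p = 0.69 with an estimated correlation; 0.085 with slide as a fixed block). Without unchallenged replicate 3 this mean was -0.22 (camera adjusted p = 0.10) and without challenged replicate 1 it was -0.26 (0.092). No gene passed by limma on day 5, with 2467 at an unadjusted p under 0.05, 741 with the replicate block, 13 with slide as a fixed block and 688 without challenged replicate 1.

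Vaccinated challenged birds were also set beside the severe and the mild non-vaccinated challenged birds. Only the non-vaccinated birds were sorted by lesions, so these comparisons cannot show that vaccination changed the response. A comparison with all non-vaccinated challenged birds was not made. On day 1 the heterophil list was lower than in severe birds by a mean of -2.20 (camera adjusted p = 2.2e-09; adjusted p = 0.023 with an estimated correlation). It was the only set test of the 16 comparisons that held with an estimated correlation. Vaccinated challenged replicate 4, at 2.73, lay inside the severe range of 2.14 to 3.88, and on slides 1, 5 and 8, which held both groups, the list differed by -2.43, -1.23 and 0.00, the pair on slide 5 being in opposite dyes. The camera call remained without each of the 8 arrays in turn. Of its 6 genes 0 passed over all genes and 4 were lower adjusted over the list alone: DEFB4A (-3.91 ± 1.08), LYG2 (-3.17 ± 1.01), LYZ (-2.71 ± 0.61) and CATH1 (-2.36 ± 0.55). DEFB4A was saturated on 2 severe arrays and LYZ on 1, so their differences are not exact. EXFABP, also in this list, was saturated on all severe arrays of day 5, so the list's differences on that day are not exact. On day 5 the same list differed by -1.39 (camera adjusted p = 0.0013; adjusted p = 0.27 with an estimated correlation), and by -0.84 on slide 7, which held both groups, with LYG2 at -3.00 ± 1.01 and LYZ at -1.76 ± 0.61 being the 2 that passed adjusted over the list alone. On day 5 the Toll-like receptor list differed by -0.33 (camera adjusted p = 0.0070; adjusted p = 0.27 with an estimated correlation) and oxidative phosphorylation genes by -0.26 (camera adjusted p = 0.028; adjusted p = 0.67 with an estimated correlation). Without vaccinated challenged replicate 1 these means were -0.10 (camera adjusted p = 0.22) and -0.08 (0.34). The oxidative phosphorylation list did not pass either without severe replicate 3 (camera adjusted p = 0.077) or 4 (0.16), and without severe replicate 1 its mean was -0.39 (0.0069). Over all genes, limma gave 0 on day 1 against severe birds (772 at an unadjusted p under 0.05, 0 with either block, 20 without vaccinated challenged replicate 4). On day 5 limma gave 1, the unnamed TC204015 at -1.09 ± 0.19, named after its value was seen (2 with the replicate block, 0 with slide as a fixed block, 0 to 4 with 1 array left out, 4 without vaccinated challenged replicate 3). Against mild birds limma gave 0 genes on day 1 (538 at an unadjusted p under 0.05) and 0 on day 5 (1079), and 0 with either block. The heterophil list differed from mild birds on day 1 by -0.74, with all 6 genes lower, 0 of them past the threshold over all genes or adjusted over the list alone. Its camera adjusted p was 0.17, while with slide as a fixed block the mean was -1.07 and passed (camera adjusted p = 0.010). On slide 5, which held mild replicate 3, it differed by -2.41.

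**Figure D3:**
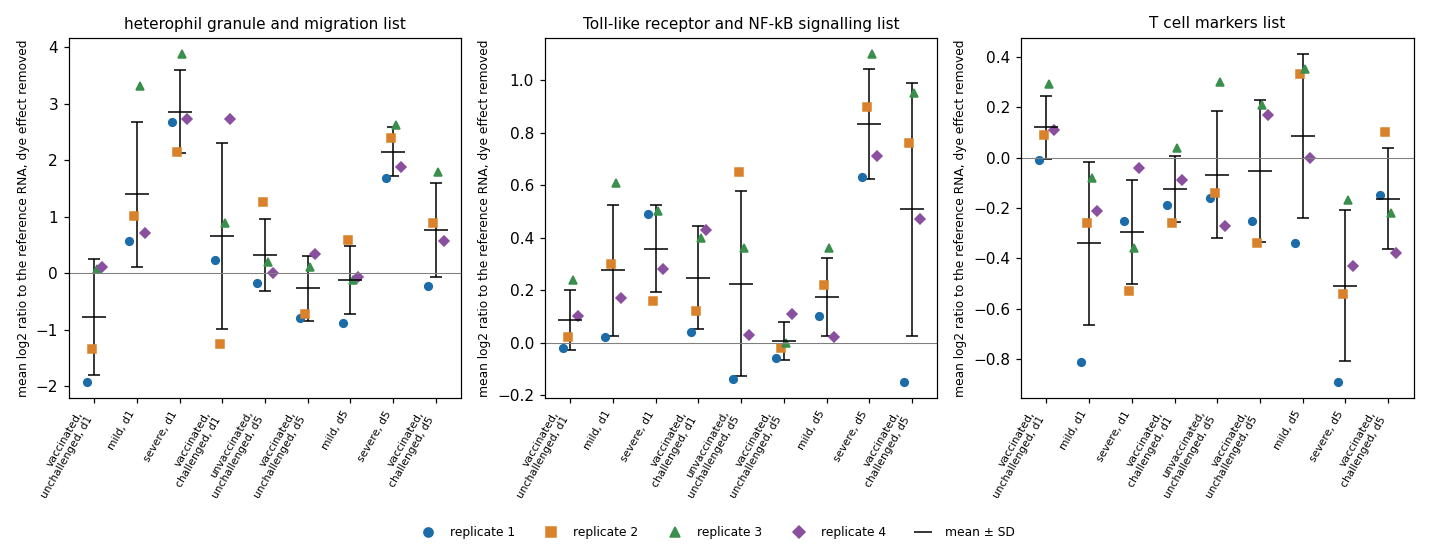
Mean log2 ratio to the reference RNA, with the dye effect removed, over the genes of 3 lists in each of the 36 arrays (points, by replicate number) with the mean and SD of each group. The 4 severe arrays of day 1 lie between 2.14 and 3.88 on the heterophil list, and 1 mild array of day 1 lies at 3.31.

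Vaccination without challenge was compared with the reference on day 1 and with non-vaccinated unchallenged birds on day 5. On day 1 the protein kinase A catalytic subunit PRKACB rose by 1.00 ± 0.17 (limma adjusted p = 0.029), the unnamed CR338800 was at 1.18 ± 0.22, and CR522995 (-0.93 ± 0.17) and CR389449 (-0.90 ± 0.13), also unnamed and chosen after their values were seen, were lower. The heterophil list had a mean of -0.77 (camera adjusted p = 0.044; adjusted p = 0.52 with an estimated correlation; 0.31 with slide as a fixed block). Its 4 arrays stood at -1.92, -1.34, 0.07 and 0.11. Without replicate 1 the mean was -0.37 (camera adjusted p = 0.46) and without replicate 2 it was -0.57 (0.22). Ribosomal protein genes had a mean of -0.22 (camera adjusted p = 0.026; adjusted p = 0.52 with an estimated correlation), which was -0.14 without replicate 1 (camera adjusted p = 0.40) and -0.10 without replicate 2 (0.22). The count of 4 was 277 with the replicate block and 103 with slide as a fixed block, and 2, 0, 1 and 9 without replicates 1, 2, 3 and 4. On day 5 no gene passed by limma (510 at an unadjusted p under 0.05, 0 with either block). Cell cycle genes were 0.20 higher in vaccinated birds on day 5 (camera adjusted p = 0.020; adjusted p = 0.70 with an estimated correlation), with adjusted p = 0.061 under the replicate block and 0.41 with slide as a fixed block, and 0 of 12 passed over all genes or adjusted over the list alone. Without vaccinated replicate 3 the mean was 0.11 (camera adjusted p = 0.28). The list did not pass either without vaccinated replicate 4 (camera adjusted p = 0.098) or non-vaccinated replicate 2 (0.22) or 4 (0.062).

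Unchallenged non-vaccinated birds of day 5 were compared with the day 1 reference as a check on the passage of time. No gene passed by limma, with 1106 at an unadjusted p under 0.05, 1 with the replicate block and 3 with slide as a fixed block. Over all 16 comparisons no set test was passed by the interferon-stimulated (smallest camera adjusted p = 0.29), lysosome and phagosome (0.26), apoptosis (0.31), heat shock (0.27), erythroid (0.25) or thrombocyte (0.22) list. In the same order, 6 of 40, 5 of 50, 7 of 39, 6 of 38, 5 of 35 and 8 of 34 listed genes were measured. These results therefore do not speak for the lists as a whole. With the replicate block the thrombocyte list passed in vaccinated birds against the reference on day 1, with a mean of 0.21 (camera adjusted p = 0.042). Lists with too few genes for a set test gave, in severe against reference birds on day 1, IL15 at -0.39 ± 0.44, IL18 at 0.06 ± 0.17 and IFNG at -0.16 ± 0.21 among cytokines, CXCR5 at 0.13 ± 0.16, EBF1 at -0.11 ± 0.15 and PIK3AP1 at -0.13 ± 0.18 among B cell markers, C1QA at 0.41 ± 0.45 and TREM2 at 0.37 ± 0.45 among monocyte markers, where LYZ rose, and CST7 at 0.05 ± 0.42 among cytotoxic markers. IL18, IFNG and EBF1 were above background on 1 of the 4 severe arrays.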

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

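The tests of swapped labels and of arrays numbered 3 for the mild array, of the reference alone, and of slide 1 were chosen after the results were seen. A gap between 1 array and the other 3 of its group marks about 1 in 20 groups by chance; here it marked 3 of 108 list means and 6 of 93 means of named genes.

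The heterophil list mean of mild replicate 3 on day 1 was 3.31, against 0.58 to 1.01 in the other 3 mild arrays. A swap with a severe bird would put a mild bird among the severe arrays, whose lowest, replicate 2, was at 2.14. That value lay above the other 3 mild arrays. They are too few to set the range of mild birds, so this does not exclude a swap. The other 8 arrays numbered 3 exceeded their groups by 0.65 ± 0.59 (SD), so a shared offset may add to the value. The excess of this array, 2.54, was larger. It was picked for its gap from its group and the other 8 were not, so a larger excess follows from the choice. The comparison therefore cannot decide whether such an offset is the only source. Of 1031 other genes called higher in severe birds on day 1, 78.5% were highest in this array among the mild ones. For the array numbered 3 in the other 7 groups the share was 12.7% to 58.1%. This array was picked as the highest of its group on the heterophil list, and those arrays were not. Genes that move with that list would be highest in it, so the share cannot decide whether it carries the wider severe profile. A swap and a shared offset stay open, as do a single wrong pathology score and a bird at an earlier or later stage, which were not tested.

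The calls of severe birds against the reference on day 1 may in part reflect the reference RNA. Against the 3 unchallenged groups 501 genes were called, 492 of them shared in direction, which argues against the reference alone as the source. Among the genes called against the reference, the median ratio of the unchallenged groups' log ratio to the severe one was 0.14 (quartiles 0.03 to 0.28), and 79.3% had the same side. The reference may therefore set part of the differences, and a true change over time or with vaccination in the unchallenged groups stays open.

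Vaccinated challenged replicate 1 on day 5 lay apart from its group: on the 688 genes called without it, its mean signed difference was 0.14, against 1.07 to 1.90 in the other 3. The highest of the 4 vaccinated unchallenged arrays was at 0.09, but the genes were chosen for a difference between these arrays and the other 3, so neither value tests a swap of labels. An effect of slide 1 cannot be told apart either: the severe day 1 array on that slide had a heterophil list mean of 2.68, but it is 1 array of another group and day. A swap, a single wrong label, the slide and a bird that did not respond to challenge could each give this value and stay open.

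The cell cycle list was at 0.06 in mild replicate 4 on day 5, against -0.14 to -0.13 in the others. The erythroid list was at 0.54 in severe replicate 2 on day 5, against 0.00 to 0.02. CATH1 was at 4.06 in severe replicate 3 on day 1, against 1.76 to 1.98. CMBL was at 3.23 in severe replicate 2 on day 5, against 1.59 to 1.75. G0S2 was at -1.49 in mild replicate 3 on day 5, against 0.22 to 0.40, and KIF21A in the same array was at 1.08, against -0.08 to 0.04. SPSB1 was at 4.05 in severe replicate 3 on day 5, against 1.99 to 2.17. ASH1L was at 1.36 in mild replicate 2 on day 5, against 0.55 to 0.60. Between days, the severe against mild difference changed by 0.58 in the Toll-like receptor list and by -0.64 in the T cell list by camera on the interaction. Both had adjusted p = 0.44 with an estimated correlation, and 0.068 and 0.37 with slide as a fixed block. With 1 array left out, 3 of 16 refits for the Toll-like receptor list and 6 of 16 for the T cell list did not pass.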

How the results depend on the processing

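Spot medians and the 3 unchallenged groups as control were chosen after seeing the data; all other alternatives were planned. Of 1694 values of named genes under alternatives, 1197 kept direction and side of the threshold, 494 kept direction only and 3 reversed; of 331 values of called lists, 223 and 108 did so and 0 reversed. Of 27 called lists, 8 remained called without each array in turn: the heterophil list in severe birds against the reference and unchallenged birds, in severe against mild and in vaccinated challenged against severe birds on both days, and the Toll-like receptor list in severe birds of day 5 against unchallenged and mild birds. Dim signal limits what could be seen, since at least 32.9% and at most 50.4% of probes were above background in the own RNA. The processed ratios of the Feature Extraction software were not run, because the scans do not hold them. Except where fewer arrays, fewer genes or the control explain a change, the cause was not tested. The reversals were CD28 in severe birds against the reference, -0.15 with the mean of its probes, and CD3D in the authors' values. CD3D was at 0.00 in severe birds against the reference and at 0.13 in severe against mild birds on day 5. The rounded 0.00 was counted as a reversal, but it shows the absence of a difference and not an opposite direction.

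Without background subtraction the counts were 29 for mild birds against the reference, 7 for challenge in vaccinated birds on day 5, 0 for vaccinated challenged against severe birds on day 5 and 1 for vaccination against the reference. Median centring gave 36 for mild birds against the reference (4 higher, 32 lower), 1 for the interaction, 2 for vaccinated challenged against severe birds on day 5, 1 for vaccination against the reference and 1 for unchallenged day 5 birds against the reference. Between-array scaling gave 28 for mild birds against the reference, 1 for severe against unchallenged birds on day 5, 397 for severe against mild birds on day 5, 17 for challenge in vaccinated birds on day 5, 0 for vaccinated challenged against severe birds on day 5 and 1 for vaccination against the reference. With no filter, 34661 genes or probes were tested and the counts were 53 for severe against unchallenged birds on day 5, 0 for vaccinated challenged against severe birds on day 5 and 2 for vaccination against the reference. With the stricter filter 9748 were tested, with 0 for each of these last 2 comparisons. The mean of probes gave 1 for vaccination against the reference.

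Slide as a random block gave 750 for severe against unchallenged and 1661 for severe against mild birds on day 5, 2 for the interaction, 1 and 318 for challenge in vaccinated birds on days 1 and 5, 2 for vaccinated challenged against severe birds on day 5 and 2 for vaccination against the reference. Slide as a fixed block gave 30 for mild birds against the reference, 1009 for severe and 1 for mild against unchallenged birds on day 5, 2 for the interaction, 17 and 13 for challenge in vaccinated birds on days 1 and 5, 0 for vaccinated challenged against severe birds on day 5, 103 for vaccination against the reference, 3 for unchallenged day 5 birds against the reference and 16 list calls in place of 27. The replicate block gave 3481 and 472 for severe and mild birds against the reference, 1575 for severe against unchallenged and 2969 for severe against mild birds on day 5, 6 for the interaction, 31 and 741 for challenge in vaccinated birds on days 1 and 5, 2 for vaccinated challenged against severe birds on day 5, 277 for vaccination against the reference and 1 for unchallenged day 5 birds against the reference. Without the dye term the counts were 800 and 1 for severe and mild birds against the reference, 4 for severe against unchallenged and 189 for severe against mild birds on day 5, 0 for vaccinated challenged against severe birds on day 5 and 0 for vaccination against the reference. Array weights gave 162 for mild birds against the reference, 335 for severe against unchallenged and 2180 for severe against mild birds on day 5, 1 for the interaction, 114 for challenge in vaccinated birds on day 5, 5 for vaccinated challenged against severe birds on day 5 and 48 for vaccination against the reference.

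The authors' values gave 1227 and 1 for severe and mild birds against the reference, 34 for severe against unchallenged and 449 for severe against mild birds on day 5, 0 for vaccinated challenged against severe birds on day 5 and 1 for vaccination against the reference. Spot medians gave 30 for mild birds against the reference and 2 for vaccination against the reference. Fits to only the groups compared gave 597 and 0 for severe and mild birds against the reference, 3 for severe against unchallenged birds on day 5, 1 for the interaction, 0 for vaccinated challenged against severe birds on day 5 and 0 for vaccination against the reference. Against the 3 unchallenged groups the counts were 501 for severe (349 higher, 152 lower) and 0 for mild birds on day 1. An estimated correlation left 1 list call and fry 6.

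With 1 array left out, counts ran from 836 to 1813 for severe and 0 to 9 for mild birds against the reference, 3 to 600 for severe and 0 to 0 for mild against unchallenged birds on day 5, 0 to 2 for severe against mild birds on day 1 and 310 to 1103 on day 5, and 0 to 2 for the interaction. They ran from 0 to 1 and 0 to 688 for challenge in vaccinated birds on days 1 and 5, 0 to 20 and 0 to 4 for vaccinated challenged against severe birds on days 1 and 5, 0 to 0 against mild birds on both days, 0 to 9 for vaccination against the reference, 0 to 0 for vaccination on day 5 and 0 to 0 for unchallenged day 5 birds against the reference.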

Other observations

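The counts over other splits of the arrays were chosen after the results were seen; the 3 relations between lists were planned before their values were computed.

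Among values not yet described, chosen after they were seen, IL15 stood at 1.43 ± 0.62 in challenged against unchallenged vaccinated birds on day 5 (limma adjusted p = 0.31) and CATH2 at 1.62 ± 0.54 in severe against mild birds on day 5 (limma adjusted p = 0.071). CD74 differed by 1.45 ± 0.37 between vaccinated challenged and severe birds on day 1 (limma adjusted p = 0.56). Of 62 probes named for genes of Marek's disease virus, 11 were above background often enough to be tested as 10 features, with 1 call over all comparisons, and their median was 2.8% of arrays above background.

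Arrays with the same replicate number deviated together, and only 8 of the 35 splits of 8 arrays part all such pairs, too few for a share under 0.05. For severe against unchallenged birds on day 5 the real count was 126, reached by 1 of 35 splits (highest other 17, and 0 among the 8); with the replicate block it was 1575 (highest other 838, and 96 among the 8). For severe against mild birds on day 5 it was 998, reached by 1 of 35 (highest other 3, and 2 among the 8); with the block it was 2969 (highest other 6). For vaccinated challenged against severe birds on day 5 it was 1, reached by 3 of 35 (highest other 32). For challenge in vaccinated birds the real counts with the block were 31 on day 1 (highest other 0) and 741 on day 5 (highest other 182). A real count of 0 is reached by every split, 35 of 35 here and 100 of 100 for the interaction, so those counts test nothing. The highest others there were 1 for mild against unchallenged birds on day 5, 52 for severe against mild birds on day 1, 12 and 40 for challenge in vaccinated birds on days 1 and 5, 92 for vaccinated challenged against severe birds on day 1, 0 and 427 against mild birds on days 1 and 5, 1 for vaccination on day 5 and 637 for the interaction. Splits with 427 and 637 genes where the groups compared gave 0 point to a structure of the samples. For the 427, the highest was 0 among the 8 splits that part all such pairs and 135 over all splits with the block. The shared replicate number may be part of it. The 8 splits are few and the block is another fit, so these values do not settle it. With the block, the highest other was also 428 for vaccinated challenged against severe birds (20 among the 8) and 131 for severe against mild birds (0 among the 8) on day 1. What the split with 637 genes follows was not tested.

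A hypothesis was that other lists move with the heterophil list from array to array within groups, tested over 36 arrays as deviations from group means by permutation within groups, 3 relations in all. The permutations did not keep arrays of the same replicate number together, so their p-values leave that pairing out. The Toll-like receptor list had r = 0.70 and rho = 0.80 (permutation p = 1e-05, the smallest that these permutations can give, adjusted p = 3e-05), with r = 0.45 to 0.87 within replicate numbers and 0.69 without the 2 farthest arrays, so the lists may share a source of variation between samples. The T cell list had r = 0.44 and rho = 0.54 (permutation p = 0.0075, adjusted p = 0.011), with r = 0.44 without the 2 farthest arrays but -0.40 to 0.48 within replicate numbers, which leaves it open. The ribosomal list had r = 0.32 (permutation p = 0.15) and rho = 0.46 (adjusted permutation p = 0.021), with r = 0.52 without the 2 farthest arrays and -0.74 to 0.38 within replicate numbers; by the bound set beforehand on r, the hypothesis was not borne out for it.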
